A study of Mus musculus with 6 samples.

How the data were processed

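Thyroid hormone receptor α (TRα), a ligand-activated transcription factor, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in gastrocnemius, the main calf muscle, of 6 mice. There were 2 mice at each of 6, 15 and 21 months of age, 3 ages in all, and each mouse had its own peak list. Per the labels' protocols, muscle was cross-linked with formaldehyde, sheared and precipitated with an antibody to TRα, and the libraries were sequenced as read pairs on an Illumina instrument.

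Per the submitters' processing notes, Trimmomatic 0.36, SAMtools 1.3.1 and MACS2 2.1.1.20160309 were used, and both GRCm39 and mm10 were named as genome builds. The aligner and the options of the peak caller are not given in the sources used here. The deposited peak names pair each immunoprecipitated library with an input library of the same mouse, so peaks were called per mouse and not on pooled mice. Scaffold names in the deposited lists belong to GRCm39, so coordinates are given as GRCm39 positions counted from 1, with chromosome names as deposited.

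The pileup column deposited by the authors is a signal, the number of fragments stacked at the summit of a peak. The fold enrichment deposited by the authors is a ratio of this pileup to the local background estimated from input. The p and q of each peak were deposited by the authors as −log10 values, and the lowest −log10 p lay between 2.00 and 2.01 in every list, so the lists hold peaks with p under 0.01 and no limit on q. These values belong to single peaks and were used only to describe, rank or filter peaks within a list. The deposited browser-format lists held the same peaks and pileups as the tables.

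The local background of each peak was recovered as (pileup + 1) / fold − 1, and the Poisson probability of a higher pileup matched the deposited p within 1% for 100% of the peaks whose p could be computed, in every list. The lowest background in a list was taken as that library's genome-wide level, and the shortest peak as its fragment length. Background divided by fragment length gave 5.49, 3.23, 3.58, 4.02, 4.03 and 3.56 fragments per kb, in the order 6, 15 and 21 months with replicate 1 before replicate 2. Read totals were not used here, so these estimates stand in for depth. At such depth a peak near the cutoff rests on 3 or 4 fragments, and the absence of a peak from a list does not show absence of binding.

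Gene names came from the deposited tables alone. In these tables annotation text of some peaks had run over into extra lines, and protein accessions in that text were matched to gene symbols with a table of the GRCm38.p6 assembly, used for names only. Such text followed 3987 of the 491681 peaks. It named 1 gene for 3812 peaks (0.775% of all peaks), left 175 unnamed and never gave more than 1 symbol. The named gene lay on the chromosome of the peak in all 3812 cases. The 395 named genes were all protein-coding, and they are genes with long pathway annotation, not a random sample of genes. Of 212 regions that carried such text and had peaks in several mice, 211 carried it for every peak. Distance to a transcription start site was not used here, so the planned promoter readouts were replaced by any peak to which a gene was assigned, at any distance.

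Peaks of the 6 mice were merged into 458111 union regions by an overlap of at least 1 bp. A region was a consensus region of an age if both mice of that age had a peak in it. Pairs of lists were compared by the Jaccard index, the bp in both lists as a percentage of the bp in either. Chance overlap was estimated by moving 1 list by 5, 10 and 20 kb in both directions, and for all 6 lists by moving each by a different multiple of such a distance. Trends with age were tested as Pearson's r with a two-sided exact permutation test over the 90 assignments of ages to mice, and Spearman's rho beside it, over a family of 10 measures with Benjamini-Hochberg adjustment. Overlap within ages was tested by exact permutation over the 15 pairings of the 6 mice, whose smallest p is 0.0667. Between 2 ages there are 3 splits of 4 mice, with a smallest p of 0.333, so single genes and regions were counted and not tested.

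Before the data were examined, 25 gene lists were fixed, covering thyroid hormone response and signalling, muscle pathways, other cell types of muscle, and ribosomal, liver and sensory receptor genes as controls. The sensory receptor list was set by a pattern of gene symbols, which 1498 protein-coding symbols of the names table match. Members were compared with the other named genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment, for lists with at least 3 named genes. This left 7 lists, since 5 lists had no named gene and 13 had 1 or 2. The genes named in the text follow a rule also fixed then, with any assigned peak in place of a promoter peak. It takes members of the thyroid hormone lists, up to 10 genes per contrast and direction ranked by the mean within-list percentile of fold of their best peak, the 10 highest-ranked genes with peaks in all 6 mice, list members in any such set, and up to 4 members of a list that passed its test. Genes named outside the rule are marked as such, and some genes that the rule takes are not reported here.

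The overlap and consensus steps were tested on simulated lists, where 400 of 400 regions planted in 6 lists and 200 of 200 planted in 2 lists of 1 age were recovered, each list holding 20000 peaks of its own. These own peaks were placed so as not to overlap, so the simulation checked the counting and says nothing on chance overlap. Alternatives were a −log10 q of at least 5, equal list lengths of 29405 peaks taken by fold, assembled chromosomes alone, a reciprocal overlap of 50%, windows of 200 bp around summits, the replicate number as a block, and each mouse left out in turn. A q of at most 0.05 and a pileup of at least 5 were added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with plots from matplotlib 3.10.9. Promoter shares and thyroid hormone response elements were not analysed here, because they need genome sequence and gene positions of the build of the lists.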

Results

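TRα ChIP-seq peak lists from gastrocnemius muscle were compared between mice of 6, 15 and 21 months, with 2 mice per age, to ask whether genomic occupancy of the receptor differed with age. The lists held 79040 and 106152 peaks at 6 months, 99436 and 29405 at 15 months, and 91661 and 85987 at 21 months. The median peak width per mouse lay between 247 and 277 bp. Most peaks were shallow, with a median pileup of 4 or 5 fragments and a median fold over input between 2.73 and 3.14. Peaks with q of at most 0.05 numbered 920 and 3233 at 6 months, 1623 and 1256 at 15 months, and 2206 and 1637 at 21 months, which was 1.16% to 4.27% of each list.

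The regions ranked highest by fold among those with a TRα peak in every mouse had folds over 100 in most lists. Of 458111 union regions, 112 had a peak in every mouse, where local shifts of the lists left 0 such regions. The number was 218 over the other 5 mice without replicate 1 at 6 months, and 61 with −log10 q of at least 5. The highest-ranked by within-list fold was at chromosome 3, 19920765 to 19921295 (GRCm39), with deposited folds from 111 to 739. The next were at chromosome 19, 40496848 to 40497534, with folds from 155 to 1543, and at chromosome 5, 98905062 to 98905402, with folds from 120 to 707. A region at chromosome 17, 50247948 to 50248506, had folds from 269 to 520. For these 4 regions, in order, the median local input background was 2.90, 8.31, 1.97 and 5.21 times the genome-wide level. The gene or gene part at these 4 positions was not analysed here. Across the 112 regions the median width was 455 bp, 77 had q of at most 0.05 in all 6 mice, and 41 had a fold of at least 10 in all 6. A further 14 of the 112 had a fold under 3 in every mouse, 11 of them with q of at most 0.05 in all 6, and their local input background was far above the genome-wide level, with a median of 401 to 513 times that level per mouse. They lay on scaffold JH584304.1 and on chromosomes 7, 9 and 17. Single lists held 44 to 211 peaks with a fold of at least 10, so not all strong peaks were shared. Of the 112, 1 lay on chromosome X, 0 on Y and 6 on unplaced or unlocalised scaffolds.

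A gene name was attached to 2 of the regions shared by all 6 mice. The region at chromosome 13, 54173594 to 54174416, was assigned to Drd1, which encodes the dopamine D1 receptor, with folds from 4.10 to 25.1. The region at chromosome 2, 49506109 to 49506370, was assigned to Kif5c, a kinesin heavy chain that moves cargo along microtubules, with folds from 3.64 to 15.2. Each reached q of at most 0.05 in 5 of the 6 mice, and the exception was replicate 1 at 6 months in both cases. A region assigned to Camk2b at chromosome 11, 5992859 to 5993460, had peaks in both mice at 15 months and both at 21 months and in neither at 6 months. Camk2b encodes a calcium/calmodulin-dependent protein kinase subunit. Its folds there were 7.92 and 4.93 at 15 months and 9.93 and 3.12 at 21 months. The peak of replicate 2 at 21 months did not reach q of at most 0.05, and the other 3 did. Replicate 1 at 6 months had weaker enrichment than the other lists, with a highest fold of 269 against 532 to 1543. It had 44 peaks with a fold of at least 10, against 108 to 211 in the other lists. The absence of a peak at this Camk2b region at 6 months therefore rests mainly on replicate 2. Camk2b had other peaks at 6 months, 5 in each mouse. This region was singled out after its values were seen.

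Most other regions were found in a single mouse. Peaks in 1 mouse alone made up 428783 regions, or 93.6% of the union, and 26270 regions had peaks in 2 mice, 2420 in 3, 378 in 4 and 148 in 5. After local shifts the corresponding numbers were 446550 regions in 1 mouse, 21189 in 2, 863 in 3, 28 in 4 and 0 in 5. The share of regions holding a peak with q of at most 0.05 rose with recurrence, from 1.55% of regions in 1 mouse to 22.1% in 3 mice and 100% in 6. A region with more peaks has more chances to hold such a peak, and the share expected from this was not computed.

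**Figure D1:**
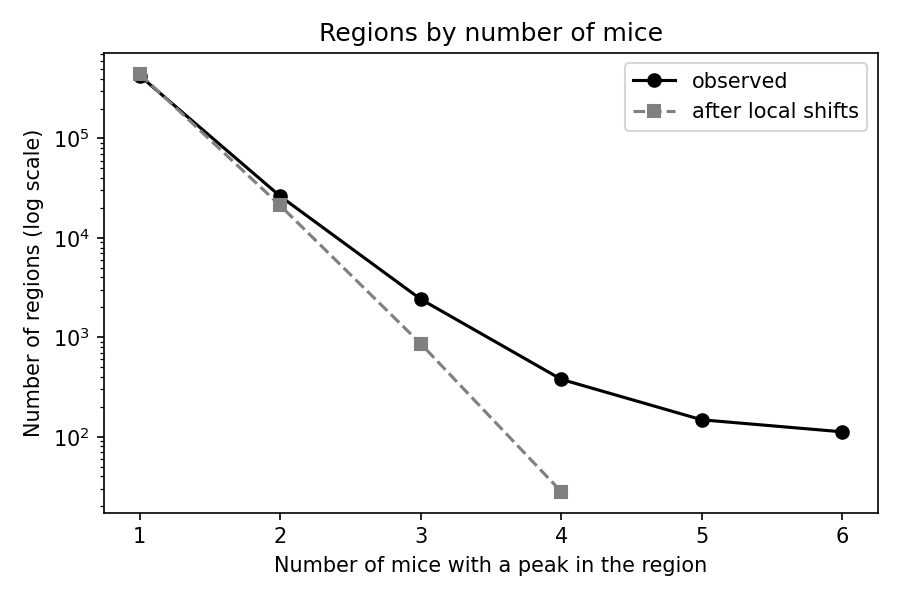
Number of union regions (y axis, log scale) by the number of mice with a peak in the region (x axis), as observed and after local shifts of the lists. Observed regions outnumber shifted ones from 2 mice upward, with 112 against 0 in all 6 mice; shifted values of 0 are not drawn.

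The number of TRα peaks did not follow age in a way that exceeded the spread between mice of one age. It was 92596 ± 19171 (SD, n = 2) at 6 months, 64421 ± 49519 (SD, n = 2) at 15 months and 88824 ± 4012 (SD, n = 2) at 21 months. Pearson's r with age was -0.12 (exact permutation p = 0.856, adjusted 0.922) and Spearman's rho was -0.12 (exact permutation p = 0.844, adjusted 1). Without the 2 mice of 6 months, the farthest from the median age, r was 0.44. Covered length was 27.6 ± 3.47 Mb at 6 months, 18.0 ± 13.9 Mb at 15 months and 26.1 ± 1.52 Mb at 21 months (SD, n = 2 each). Its r with age was -0.15 (exact permutation p = 0.756, adjusted 0.922), its rho was -0.36 (exact permutation p = 0.533, adjusted 1), and r without the mice of 6 months was 0.50. The mean at 15 months rests on replicate 2, whose list was the shortest. With a pileup minimum of 5 in every list, a choice made after seeing the data, the numbers were 66311 and 26713 at 6 months, 30268 and 22443 at 15 months, and 36976 and 27641 at 21 months. The adjusted p was 0.922 for every one of the 10 measures tested against age by Pearson's r in exact permutation tests.

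**Figure D2:**
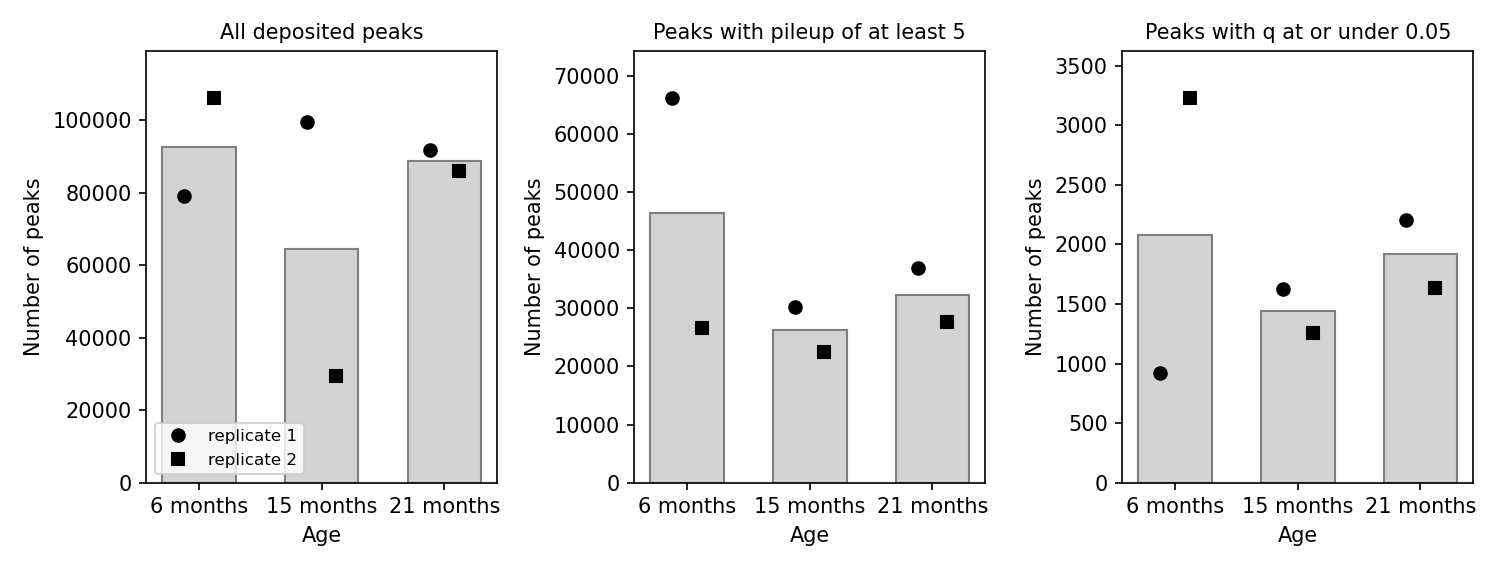
Number of peaks per mouse (y axis) by age (x axis) for all deposited peaks, for peaks with a pileup of at least 5, and for peaks with q of at most 0.05. Points are single mice and bars are means of 2 mice; replicate 2 at 15 months has the fewest peaks in the first panel (29405) and the second (22443, next to 26713 in replicate 2 at 6 months), and replicate 1 at 6 months the fewest in the last (920).

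No excess of shared peak area was detected between mice of the same age over mice of different ages. The Jaccard index was 0.930% ± 0.192 (SD, n = 3 pairs) within ages and 0.917% ± 0.179 (SD, n = 12 pairs) between ages. Of the 15 pairings of the mice, 6 gave a difference as large as the pairing by age, itself included (exact permutation p = 0.4, with 0.0667 the smallest possible). A median of 3.35% of the peaks of a mouse were overlapped by a peak of another, against 2.13% after local shifts. Among peaks with q of at most 0.05 the median was 18.2% against 2.43% after shifts, and among peaks with a fold of at least 10 it was 72.2%, with a range over ordered pairs of 39.8% to 95.5%.

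**Figure D3:**
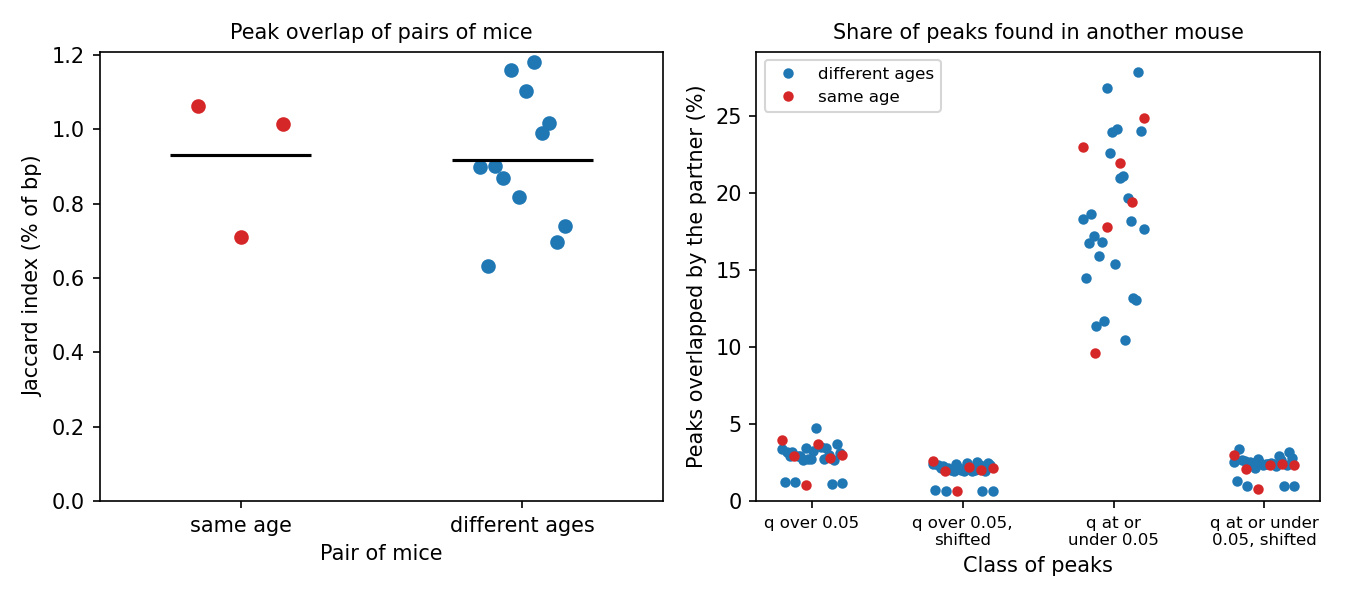
Left, Jaccard index (% of bp) for the 3 pairs of mice of the same age and the 12 pairs of different ages, with horizontal lines at the means of 0.930% and 0.917%. Right, percentage of a mouse's peaks overlapped by a partner's peaks, by q class and after local shifts, one point per ordered pair. At q of at most 0.05 pairs of the same age span 9.59% to 24.9% and pairs of different ages 10.5% to 27.8%.

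Consensus regions, with a peak in both mice of an age, numbered 3391 at 6 months, 1391 at 15 months and 3001 at 21 months. Local shifts of 1 list gave 2075, 653 and 1864, so the observed numbers were 1.63, 2.13 and 1.61 times those. This order of the ages turned under other settings, with 578, 659 and 712 regions at 6, 15 and 21 months for equal list lengths, 117, 216 and 289 at q of at most 0.05, and 73, 158 and 192 at −log10 q of at least 5. Replicate 1 at 6 months had the fewest peaks under both limits on q. At −log10 q of at least 5 it had 102, against 438 in replicate 2 at 6 months and 207 to 420 in the other mice. The low counts at 6 months under these limits cannot be told apart from the shortness of that list. The total over ages was 7783, and the other 14 pairings of the mice gave 7391 to 8093. Regions with peaks in both mice of 1 age and none of the other 4 mice numbered 2454, 739 and 2098 at 6, 15 and 21 months, and such regions of pairs of different ages numbered 652 to 2720. With q of at most 0.05 in both mice, age-restricted regions numbered 7 at 6 months, 13 at 15 months and 18 at 21 months, against 2 to 41 for pairs of different ages. The highest-ranked of these at 6 months was at chromosome 14, 91664227 to 91664544, with folds of 12.1 and 74.7. At 15 months it was at chromosome 4, 144492642 to 144493347, with folds of 23.0 and 12.7. At 21 months it was at chromosome 8, 50190032 to 50190495, with folds of 13.8 and 12.9. No gene name was attached to these 3 regions, which were singled out after their values were seen.

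Genes could be named for few peaks, and 395 genes were named in at least 1 mouse. Peaks were assigned in both mice of an age to 171 genes at 6 months, 130 at 15 months and 170 at 21 months, and 73 genes had peaks in all 6 mice, mostly at different positions. Of the 73, 2 had a region shared by all 6 mice, 10 had one shared by at least 3 mice, 29 had none shared by any pair of mice, and 26 had at least 1 peak with q of at most 0.05. The 10 highest-ranked of the 73 by fold of their best peak were Drd1, Kif5c, Atg7, Grin2a, Prox1, App, Fzd1, Tlr4, Foxp2 and Enpp1. Atg7, an E1-like enzyme of autophagosome formation, had 75 peaks over the 6 mice and a mean best fold of 4.01 ± 0.334 (SD, n = 6). Grin2a, an NMDA receptor subunit, had 95 peaks and a mean best fold of 3.93 ± 0.269 (SD, n = 6). Prox1, a homeobox transcription factor, had 29 peaks and a mean best fold of 3.99 ± 0.451 (SD, n = 6). Tlr4, a receptor for bacterial lipopolysaccharide, had 47 peaks, and Fzd1, a Wnt receptor, had 62. Few of these peaks had q of at most 0.05, with 3 for Atg7, 1 for Grin2a, 3 for Prox1, 0 for Tlr4 and 2 for Fzd1. No position of these genes was shared by more than 3 mice, so the mean best folds include peaks at different positions. A gene with more peaks also has more chances of a high best fold.

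Of the thyroid hormone response genes, 2 of 28 were named, and of the thyroid hormone signalling machinery 3 of 30. Ppargc1a, a coactivator of mitochondrial biogenesis, had peaks in all 6 mice, with 5 and 9 at 6 months, 4 and 2 at 15 months, and 8 and 7 at 21 months. Rxra, the retinoid X receptor that pairs with thyroid hormone receptors on DNA, also had peaks in all 6, with 2 and 2, 2 and 1, and 3 and 4 peaks at the 3 ages. None of these peaks of Ppargc1a and Rxra had a q of at most 0.05, no position of Ppargc1a was shared by more than 2 mice, and no position of Rxra was shared by any pair of mice. Peaks of Crebbp, a histone acetyltransferase, were found in 3 mice, those of Med1, a Mediator subunit, in 2 mice, and a single peak of Hk2, a hexokinase, in 1 mouse. None of these 5 genes had peaks in both mice of one age and neither of another. The other members, among them Thra and Thrb, were not named by the annotation text, and their occupancy was not analysed here.

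Between 6 and 15 months, 13 genes had peaks in both younger mice and neither older mouse, and 8 had the opposite pattern. The 10 highest-ranked at 6 months were Arrb1, Lyn, Pde2a, Sfrp5, Itgav, Aplp2, Yes1, Aurka, Fgfr1 and Insrr. Arrb1, which encodes β-arrestin 1, had a best fold of 4.61 ± 2.13 (SD, n = 2), and Lyn, a Src-family kinase, 3.50 ± 0.617 (SD, n = 2). The members of fixed lists were Ccl5, a chemokine of the inflammation list, and Akt1, a kinase of the insulin, IGF and mTOR list. The 8 genes with peaks at 15 and not at 6 months were Hdac1, Wnt7b, Prkaa1, Aqp1, Dnm1, P2rx7, Grm4 and Itga8. Hdac1, a histone deacetylase, had a best fold of 3.50 ± 0.0577 (SD, n = 2), and Prkaa1, a catalytic subunit of AMP-activated protein kinase, 2.85 ± 0.147 (SD, n = 2). No position of Arrb1, Lyn, Hdac1 or Prkaa1 was shared by any pair of mice, so each mean is over peaks at different positions. Among the 13 and 8 genes of this contrast, only Arrb1 and Pde2a had a peak with q of at most 0.05. The other 2 splits of these 4 mice gave 1 to 38 genes per direction, a range that holds both counts. The larger side turned with equal list lengths, to 8 at 6 and 18 at 15 months, and without replicate 2 at 15 months, to 21 and 31. At q of at most 0.05 the counts were 0 and 1.

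Between 6 and 21 months, 12 genes had peaks in both mice at 6 and neither at 21 months, and 9 the opposite. The 10 highest-ranked at 6 months were Ccr4, Arrb1, Scarb2, Bmp6, Ceacam13, Aurka, Ins2, Parp1, Fgfr4 and Akt1. Ccr4, a chemokine receptor, had a best fold of 3.94 ± 0.0715 (SD, n = 2), and Bmp6, a bone morphogenetic protein, 3.22 ± 0.178 (SD, n = 2). The 9 at 21 months included Itga8, P2rx7, Pax5, Atp7a, Prkaa1, Map2k2 and Il6. Itga8, an integrin subunit, had a best fold of 3.63 ± 0.583 (SD, n = 2), and Il6, a cytokine that contracting muscle releases, 2.56 ± 0.507 (SD, n = 2). No position of Ccr4, Bmp6, Itga8 or Il6 was shared by any pair of mice, and none of their peaks had q of at most 0.05. The other splits gave 11 to 22 genes, so the 9 genes at 21 months were fewer than either other split gave. The counts were 1 and 0 at q of at most 0.05, 0 and 0 at −log10 q of at least 5, and 22 and 9 with a pileup of at least 5. The larger side turned without replicate 2 at 6 months, to 29 at 6 and 40 at 21 months, and without replicate 1 at 21 months both counts were 28.

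Between 15 and 21 months, 8 genes had peaks in both mice at 15 and neither at 21 months, and 18 the opposite. The 8 were Bmp6, Pak2, Dll4, Acvr1, Myh7b, Wnt7b, Dnm1 and Fgfr4. Myh7b, a myosin heavy chain, had a best fold of 3.25 ± 1.24 (SD, n = 2), and Acvr1, a receptor for bone morphogenetic proteins, 3.09 ± 0.641 (SD, n = 2). No position of Myh7b or Acvr1 was shared by any pair of mice, and none of their peaks had q of at most 0.05. The 10 highest-ranked at 21 months included Tfap2e, Plcb2, Fgfr1, Pak3, Atp7a, Grm2, Itgb2, Aplp2 and Itgb2l, and the fixed lists also held Il6 and Ccl5. These 18 genes had peaks in neither mouse at 15 months, where replicate 2 had 247 gene-named peaks against 583 to 848 in the other 5 mice. The other splits gave 5 to 36 genes. The larger side turned with equal list lengths, to 19 at 15 and 8 at 21 months, with a pileup of at least 5, to 16 and 12, and without replicate 2 at 15 months, to 39 and 21. At q of at most 0.05 both counts were 0. Genes with peaks in both mice of 1 age and in none of the other 4 mice numbered 3 at 6 months (Akt1, Arrb1 and Aurka), 2 at 15 months (Dnm1 and Wnt7b) and 5 at 21 months, among them Atp7a, Il6 and Map2k2. These counts compare with 0 to 9 for pairs of mice of different ages.

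No gene list passed its test at any age. Lists with 3 to 5 named genes could not have passed alone in 21 tests, even with peaks of every member, so their tests decide nothing. Nor could the 6 named muscle atrophy genes at 6 or at 21 months, so those tests decide nothing either. No control list had enough named genes to be tested. The lowest p was that of inflammation and NF-κB genes at 21 months, with 8 of 10 named members having peaks in both mice, against 42.1% of other genes (Fisher's exact p = 0.0223, adjusted 0.469, and 0.0670 adjusted over the list alone). At 6 and at 15 months 5 of these 10 had peaks in both mice, and the difference between ages was not tested. Tlr4, Nfkb1, Ikbkb and Tgfbr1 had peaks in all 6 mice, and Jak2, Tgfbr2, Il6 and Ccl5 were the other members with peaks in both mice at 21 months. Of these 8 genes, only Jak2 had a peak with q of at most 0.05 at 21 months, in replicate 1. Of the insulin, IGF and mTOR genes, 7 of 14 had peaks in both mice at 6 months, 4 at 15 months and 8 at 21 months (lowest Fisher's exact p = 0.288, adjusted 1). Igf1r and Gsk3b were among the members with peaks in all 6 mice. Of the muscle atrophy genes, 3 of 6, 1 of 6 and 3 of 6 had peaks in both mice at 6, 15 and 21 months. Traf6, a ubiquitin ligase, had peaks in all 6 mice, whereas Foxo3 and Smad3 lacked peaks in 1 mouse each. Of the autophagy genes, 1 of 3, 2 of 3 and 1 of 3 had peaks in both mice at the 3 ages. Of the myogenic regulators, 1, 1 and 2 of 5 did so, with Mef2c, a transcription factor of muscle differentiation, in all 6 mice. Of the senescence genes, 1, 1 and 2 of 4 did so, with the kinase Atm in all 6 mice. Of the thyroid hormone signalling machinery, 1 of 3 did so at each age. None of the peaks of Igf1r, Gsk3b, Traf6, Mef2c and Atm had q of at most 0.05. No position of these genes was shared by more than 2 mice. Over these 21 tests, 1 had an unadjusted p under 0.05 by Fisher's exact test and 0 an adjusted one. Among genes with peaks at one age and not another, 0 of 42 Fisher's exact tests had an unadjusted p under 0.05, with an adjusted p of 1 throughout.

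Lists too short to test were described by their named members. Camk2b and Camk2a stood for calcium handling, Cd36 and Ppard for fatty acid metabolism, Hk1 and Hk2 for glucose metabolism, Mfn2 for mitochondrial dynamics, Ppargc1a for mitochondrial biogenesis and Sod1 for antioxidant defence. Cd36, a fatty acid transporter, had 41 peaks and was found in all 6 mice. None of its peaks had q of at most 0.05, and no position was shared by more than 2 mice. Among other cell types, Flt1 and Kdr stood for endothelial cells, Pparg and Lep for adipocytes, Pdgfra for fibroblasts, and Erbb3 for both Schwann cells and the neuromuscular junction. Flt1, a receptor for vascular endothelial growth factor, had peaks in all 6 mice, none with q of at most 0.05. No position of Flt1 was shared by more than 2 mice. Apoa1, an apolipoprotein of the liver control list, had peaks in 5 mice. The 5 lists with no named gene were the sarcomere, the circadian clock, ribosomal proteins, macrophages with other leukocytes, and sensory receptors.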

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

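The settings with q at or under 0.05 and with a pileup of at least 5 were chosen after seeing the data. Of 188 values under alternatives, 108 were counted as kept, 70 moved and 10 reversed. Kept means the same direction and side of the threshold for a test, within 1.5 times for a count, and within the spread over the other pairings for the consensus ratio. No trend with age and no gene list passed its threshold under any alternative run, but with limits on q the age-restricted sets held at most 1 gene, so their list tests say nothing there. The cause was not tested for any change below, except where fewer peaks or fewer mice make the count smaller or larger by construction.

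With −log10 q of at least 5, r with age was 0.28 for peak number and 0.30 for covered length, and the within-age minus between-age Jaccard fraction was -0.0154. Consensus regions numbered 73, 158 and 192 at 6, 15 and 21 months, 61 regions were in all mice, the ratio of consensus regions to the other pairings was 0.9504, and each of the 6 gene counts was 0. With equal list length the Jaccard difference was -0.000252, and consensus regions numbered 578, 659 and 712. Gene counts were then 8 at 6 and not 15 months, 18 at 15 and not 6, 19 at 15 and not 21, and 8 at 21 and not 15, so the larger count changed sides in both contrasts that involve 15 months. A reciprocal overlap of 50% gave 1456, 711 and 1395 consensus regions. With q at or under 0.05 there were 117, 216 and 289, and gene counts were 1 at 15 and not 6 months, 1 at 6 and not 21 months, and 0 for the other 4. With a pileup of at least 5 the Jaccard difference was -0.000751, consensus regions numbered 1290, 773 and 1087, and gene counts were 26 at 6 and not 15 months, 22 at 6 and not 21, and 16 at 15 and not 21 against 12 at 21 and not 15, where the larger count also changed sides. The order of the ages by consensus regions turned with equal list length and with both limits on q. Replicate 1 at 6 months had the fewest peaks under both limits on q.

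With each mouse left out in turn, the other mouse stood alone for its age. Then r ranged from -0.24 to 0.18 for peak number and from -0.35 to 0.090 for covered length, turning positive without replicate 2 at 6 months. The Jaccard difference ranged from -0.00101 to 0.00172, regions in all mice from 114 to 218 (218 without replicate 1 at 6 months), and the consensus ratio from 0.829 to 1.34, its highest without replicate 1 at 15 months. Consensus regions, which for a lone mouse are its own peaks, ranged from 3358 to 106152 at 6 months, 1373 to 99436 at 15 months and 2973 to 91661 at 21 months. Gene counts ranged from 13 to 75 for 6 and not 15 months, 8 to 31 for 15 and not 6, 12 to 45 for 6 and not 21, 9 to 40 for 21 and not 6, 8 to 39 for 15 and not 21, and 18 to 71 for 21 and not 15. Without replicate 2 at 15 months the larger count changed sides in both contrasts that involve 15 months, and without replicate 2 at 6 months it did so between 6 and 21 months (29 at 6 and 40 at 21 months). Without replicate 1 at 21 months these were 28 and 28.

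Replicate numbers only name the mice. The replicate 1 lists were above their age mean in 2 of 3 ages. With 3 ages this count cannot show whether same-numbered mice deviated together. With the replicate number as a block, r was -0.12 for peak number (exact permutation p = 0.889) and -0.17 for covered length (exact permutation p = 0.806), over 36 arrangements, and no call changed.

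Not run were all planned promoter definitions, the universe of genes from a reference annotation, and the response element settings, which need positions or sequence not used here. How far depth limits the lists was not tested.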

Other observations

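The peaks assigned to list genes with at least 10 peaks were set against age as peaks per 10000 of each list. This comparison was chosen after seeing the data, as were all tests in this part except the one on strong peaks of chromosome X. Of 24 genes, 0 had an unadjusted p under 0.05 in exact permutation tests over 6 mice. Flt1, the vascular endothelial growth factor receptor, had 0.378 ± 0.00194 peaks per 10000 at 6 months, 0.472 ± 0.186 at 15 months and 0.843 ± 0.0415 at 21 months (SD, n = 2 each; r = 0.84, exact permutation p = 0.0667, adjusted 0.467). Ikbkb, a kinase that activates NF-κB, had 0.362 ± 0.154, 0.271 ± 0.0982 and 0.113 ± 0.00509 at the same ages (SD, n = 2 each; r = -0.78, exact permutation p = 0.0667, adjusted 0.467). Traf6 had 0.252 ± 0.177, 0.421 ± 0.115 and 0.738 ± 0.272 at the same ages (SD, n = 2 each; r = 0.79, exact permutation p = 0.0667, adjusted 0.467). Tlr4 had 1.23 ± 0.407, 0.843 ± 0.230 and 0.734 ± 0.113 (SD, n = 2 each; r = -0.72, exact permutation p = 0.0778, adjusted 0.467). Rxra had 0.221 ± 0.0457, 0.271 ± 0.0982 and 0.396 ± 0.0975 (SD, n = 2 each; r = 0.73, exact permutation p = 0.122, adjusted 0.587). Some of these rates rest on few peaks. Flt1 had 3 and 4 peaks at 6 months, 6 and 1 at 15 months, and 8 and 7 at 21 months. Ikbkb had 2 and 5, 2 and 1, and 1 and 1 peaks at these ages. With equal counts, as for Ikbkb at 21 months, the SD shows only the difference in list length.

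Among gene-named regions, Camk2g and Pink1 each had a region with q of at most 0.05 in 2 mice of different ages. That of Camk2g was at chromosome 14, 20816914 to 20817252, and that of Pink1, a mitochondrial kinase that marks damaged mitochondria, at chromosome 4, 138061721 to 138061921. Gata4, a transcription factor of heart development, had one at chromosome 14, 63493160 to 63493509.

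Replicate 2 at 15 months had 29405 peaks, 0.321 times the median of the other 5 lists. Lower depth is argued against, since 3 of the other 5 libraries had fewer background fragments per kb than its 4.02. Age alone is argued against too, since the other list at 15 months held 99436 peaks, above the median of 88824 over the 4 lists of the other ages. The whole-number cutoff of the caller stays open, because a pileup of 3 at its background had a Poisson p of 0.01002, just over the cutoff, against 0.00961 for replicate 1 at 21 months. Replicate 1 at 6 months was also held to a pileup of 4 (Poisson p of 0.0334 at 3), yet its list had 79040 peaks. Its background was higher, with a Poisson p of 0.00765 at a pileup of 4 against 0.00160 for replicate 2 at 15 months. With a pileup minimum of 5 in every list the ratio was 0.741, but with a minimum of 4 it was 0.395, so the cutoff cannot be told apart from other causes without calling peaks anew at 1 cutoff.

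Sequence that also gathers reads in input is argued against as the cause of all 112 regions with a peak in every mouse, since the median local background over these regions was at most 1.84 times the library's floor (lowest mouse 1.24). It stays open for part of them, since 24 of the 112 had a background of 5 or more times the floor and 70 had one under 2. Fold is relative to that background, so a split of the regions by fold says nothing on this question. No biological explanation was tested, since no mouse without TRα and no precipitation with a control antibody were analysed here.

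Chromosome X held 9924 peaks against 466412 on autosomes, a density ratio of 0.309 over all lists, and the sex of the mice was not analysed here. If fewer X copies acted at the calling cutoff, strong peaks should be depleted less, and for peaks with a fold of at least 10 the ratio was 0.284 (exact 95% interval, for counting error only, 0.165 to 0.458, 17 peaks on X). For peaks with q of at most 0.05 it was 0.358 (exact 95% interval 0.315 to 0.406, 252 peaks on X), above 0.309. Of these 252 peaks, 104 came from replicate 2 at 6 months. Against all peaks the ratio was lower in replicate 1 at 15 months (0.265 against 0.291) and replicate 1 at 21 months (0.264 against 0.402). It was higher in every other mouse. Fewer copies would also lower the fold where the background is at the genome-wide level, so a minimum fold acts as a cutoff too. A region with strong peaks in several mice was counted once per mouse, so the intervals treat repeats as separate. From these ratios, fewer X copies cannot be told apart from an equal depletion. Peaks per Mb were 2.13 to 14.01 on X, 4.50 to 35.9 on Y and 11.6 to 40.8 on autosomes, with Y above X in every mouse, which copy number alone would not give, but repeated sequence on Y was not analysed here. The ratio per mouse had an r of 0.44 with age (exact permutation p = 0.378), with 0.278 ± 0.0699, 0.238 ± 0.0758 and 0.365 ± 0.0516 at 6, 15 and 21 months (SD, n = 2 each), and an effect of age stays open.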
